A study of Rattus norvegicus with 12 samples.

How the data were processed

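Noncoding RNA was measured in 12 samples of fetal rat lumbosacral spinal cord at embryonic day 19, 6 for miRNA and 6 for lncRNA, with 3 normal and 3 ARM samples in each. The deposited miRNA table gives raw counts per mature miRNA and TPM per the file headers; the deposited TPM values equal the count scaled to the column total (largest gap 0.000519) and have no length term. The deposited lncRNA table gives raw counts per transcript per the file headers, with coordinates and lengths. Its 6 FPKM columns were not used here. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff for all samples, with no role or order, and a mouse build, whereas the identifiers and coordinates are of rat. The build of the coordinates, the counting tool and the strand setting are not given in the sources used here. Counts of 1 were more regular than random sampling gives: of 697 transcripts with 6 counts in total, 408 (58.5%) had 1 in each library, against 1.54% if counts were spread at random. Intervals and floors cover counting error only.

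Columns were matched to samples by their headings. The headings of the 3 normal lncRNA columns differ in form from the others and were matched to the group, so their numbers are names and no paired fit was made for lncRNA. The 22591 transcripts carried 20418 NONRATT, 949 ENSRNOT and 1224 MSTRG identifiers. A current rat gene symbol was found for 8253 of them, 8188 from AceView locus names, 37 from RefSeq accessions and 28 from Ensembl names. A symbol names the locus and does not mean that the transcript is the gene's messenger RNA. Transcripts with overlapping coordinates, whatever their strand, formed 18074 clusters.

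Each table was tested on its own with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter, a quasi-likelihood fit with phenotype alone and Benjamini-Hochberg adjustment with a threshold of 0.05. This kept 467 of 753 miRNAs and 13343 transcripts. The SE is the absolute log2 fold change divided by the square root of the F statistic. Where a group had 0 counts in all libraries, the fold is a bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio has a 95% Clopper-Pearson interval. Library measures were compared by two-sided exact permutation tests, which cannot go below 0.1 here.

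Before the data were examined, 20 miRNA lists and 23 lncRNA lists were fixed for the cell types, pathways and genomic clusters of the tissue and of neighbouring tissues, together with the design, the alternatives and the rule for named features. Lists were tested with camera in limma 3.58.1, two-sided with a preset correlation of 0.01, where at least 3 members were tested, which held for 16 miRNA and 14 lncRNA lists. Members of the lncRNA lists are noncoding transcripts carrying the symbol. The imprinted, microRNA-host and nuclear lists share the 9 tested Meg3 transcripts, and overlapping transcripts of a locus are not independent.

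Named features were, per table, up to 10 higher and 10 lower by size of change among those past the threshold with all 3 ARM libraries on one side of all 3 normal ones and a mean of at least 10 counts in the higher group. Where fewer than 5 passed, the 5 higher and 5 lower with the smallest unadjusted p were named as not passing. From each list the members past the threshold, at most 4, or else the 2 with the highest mean were named, with the 5 most abundant features and the host lncRNAs of listed miRNAs. Features without a symbol are named by AceView locus name where the table has one; by identifier alone, at most 2 higher and 2 lower were to be named. Some features that the rule takes are not reported here. The miR-196a-5p, miR-122-5p, NONRATT005941.2, NONRATT005943.2, NONRATT011162.2, NONRATT016570.2, MSTRG.5726.2 and MSTRG.9548.2 values, and the miR-741 and miR-743 group, were singled out after their values were seen.

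Alternatives were DESeq2 1.42.0, its size factors within edgeR, total-count scaling, no filter, a filter at a mean of 10 CPM, limma-voom, a replicate block (miRNA), scaling without the 5 most abundant miRNAs, a threshold of 0.1, an added minimum log2 fold change of 1, each library left out in turn, an estimated correlation and fry. Counts summed over overlapping transcripts, the nuclear list without Meg3 and the patterning list without its called transcript were added after seeing the data. Every split of the 6 libraries of each table into 3 and 3 was also fitted. The pipeline was tested on simulated data: edgeR found 51 of 57 miRNAs changed 2-fold and 74 of 74 changed 4-fold, and 2 of 64, 39 of 64 and 52 of 59 transcripts changed 2-fold, 4-fold and 8-fold. Of its calls, 8 of 199 and 9 of 102 were false, and of the unchanged lists camera called 0 of 11 and 1 of 11. The simulated features were drawn independently and the lists were random features. These rates therefore do not cover lists with correlated members, or transcripts that drop to near 0 in some libraries whatever the phenotype. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.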

Results

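Small and long noncoding RNA were measured in the lumbosacral spinal cord of rat fetuses at embryonic day 19. The fetuses were either normal or had anorectal malformations (ARM) induced with ethylenethiourea, a thyroid-suppressing teratogen given to the dam. By the labels every ARM sample was exposed and no exposed sample lacked ARM. Effects of the exposure and of the malformation therefore cannot be told apart, and phenotype here means both. The 12 samples formed 4 groups of 3: normal and ARM libraries for microRNA (miRNA, replicates 4 to 6) and normal and ARM libraries for long noncoding RNA (lncRNA, replicates 1 to 3). In each group miRNA replicates 4 to 6 carry the same label codes as lncRNA replicates 1 to 3. The miRNA and lncRNA libraries may therefore come from the same tissues, and the results of both tables may not be independent. The miRNA libraries held 11230621 to 13832152 counts over 753 mature miRNAs, and the lncRNA libraries held 3285614 to 3865088 counts over 22591 transcripts. A count of 0 allowed up to 0.217 to 0.267 CPM (counts scaled to library size) in a miRNA library and 0.776 to 0.913 CPM in an lncRNA library. Nothing in the labels says whether the replicates came from separate animals or litters, so the p-values measure only the spread between these samples. Below, values in CPM are mean ± SD over 3 libraries, and log2 fold changes are ARM over normal with their standard error (SE).

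The most abundant miRNA in both groups was miR-9a-5p, which is typical of neural tissue. It took 31.0% to 34.1% of the counts of each library, and the 5 most abundant miRNAs (miR-9a-5p, miR-99a-5p, miR-10a-5p, let-7i-5p and miR-125b-5p) took 57.8% to 59.5%. Their log2 fold changes were 0.07, -0.11, 0.22, -0.03 and -0.08. ARM libraries had 571 ± 1.00 detected miRNAs and normal libraries 558 ± 3.79 (n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 allow). Totals did not separate the groups (exact permutation p = 0.9 for miRNA and 0.4 for lncRNA). In the lncRNA libraries the 5 most abundant transcripts took 8.68% ± 0.483 of counts in ARM and 7.65% ± 0.296 in normal (n = 3 each; two-sided exact permutation p = 0.1).

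The first comparison asked which miRNAs differ between ARM and normal spinal cord. Tested as groups with a preset correlation, the sensory miR-183 cluster, the miRNAs embedded in the Hox gene clusters and the miR-17 family clusters were higher in ARM, and the miRNAs of liver, gut and kidney were lower. These calls were lost with an estimated correlation (adjusted p = 0.202, 0.202, 0.528 and 0.202 with an estimated correlation, in this order) and without ARM replicate 6. All 4 tested members of the miR-183 cluster, which is expressed in sensory neurons, had higher estimates. For miR-96-5p the level was 158 ± 26.1 CPM in normal and 264 ± 51.8 CPM in ARM (log2 fold change 0.74, SE 0.17), for miR-182 it was 1658 ± 74.7 and 2335 ± 392 CPM (0.49, SE 0.13), and for miR-183-5p 753 ± 57.7 and 983 ± 90.5 CPM (0.38, SE 0.11). For these 3 miRNAs the groups did not overlap, with every ARM library above every normal library. Chance separates the groups in one direction or the other for 10% of unchanged miRNAs. The 3 are not separate observations, since the estimated correlation of the members of this list was 0.567. Of the 11 Hox-embedded miRNAs, most of them paired 5p and 3p arms, 10 had higher estimates, among them miR-10a-5p (0.22), miR-10b-5p (0.19) and miR-196a-5p (0.30). In the miR-17 and paralogous clusters, linked to proliferation, 13 of 17 had higher estimates, with miR-19a-3p at 0.38, miR-20a-5p at 0.22 and miR-25-3p at 0.04 (-0.0020 without normal replicate 4). All 4 members of the liver, gut and kidney list had lower estimates, with miR-192-5p at -0.30, miR-194-5p at -0.25 and miR-122-5p at -2.21, the last of which had 1059 counts in 1 normal library and 17 to 164 in the other 5 and was at 0.64 without that library, normal replicate 4.

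Camera with a preset correlation called these 4 of 16 lists. The camera adjusted p was 2.79e-06 for the miR-183 cluster, 0.000479 for the Hox-embedded list and 0.0111 for both the miR-17 clusters and the liver list. With an estimated correlation it was an adjusted p of 0.202, 0.202, 0.528 and 0.202. The estimates were 0.567, 0.0797, 0.127 and -0.186, in this order. For the liver list the estimate was below the preset 0.01, yet the unadjusted camera p rose from 0.00278 to 0.0380. A higher correlation therefore does not explain the loss of that list. Without ARM replicate 6 none of the 16 lists was called, with camera adjusted p of 0.140 for the miR-183 cluster, 0.184 for the Hox-embedded list, 0.669 for the miR-17 clusters and 0.140 for the liver list. Without normal replicate 4 the count was 2, with 0.172 for both the miR-17 clusters and the liver list, and without ARM replicate 4 the count was 7, adding the epithelium (0.000375), skeletal muscle (0.00185) and mesenchyme (0.0429) lists as lower. The miR-17 clusters were also lost without normal replicate 6 (0.199) and the liver list without ARM replicate 5 (0.157).

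No single miRNA passed: edgeR called 0 of 467 tested miRNAs, with 29 at an unadjusted p under 0.05 and a smallest adjusted p of 0.318. Of the 29, 19 had higher and 10 lower estimates, and other splits of the 6 libraries into 3 and 3 gave up to 47. Limma-voom also called 0 and DESeq2 called 6, all higher in ARM: miR-182, miR-96-5p, miR-471-5p, miR-743a-3p, miR-743b-3p and miR-878, of which those outside the naming rule were named after their values were seen. Without ARM replicate 6, edgeR called 9, all higher. All of them belong to the miR-741 and miR-743 group given below, which among the ARM libraries was low only in the one left out. Those with the smallest unadjusted p that did not pass were, among the higher estimates, the miR-183 cluster members and miR-19a-3p already given and miR-741-3p (4.08, SE 0.94). The lower ones were miR-187-3p (-0.46, SE 0.13), miR-192-5p (-0.30, SE 0.11), miR-1306-3p (-0.52, SE 0.21), miR-150-5p (-0.27, SE 0.11) and the endothelial miR-126a-3p (-0.41, SE 0.17). The counts of miR-741-3p were 8, 1 and 16 in normal and 182, 190 and 13 in ARM. Adjusted over the list alone, 3 members of the miR-183 cluster passed (smallest edgeR adjusted p 0.00463), and did so in all 6 fits that left out 1 library (highest 0.0437). That adjustment covers the 4 tested members and not the other lists. The 6 fits share libraries and are not repeated support. Adjusted over the list alone, both endothelial miRNAs, miR-126a-3p and miR-126a-5p (-0.32), had an edgeR adjusted p of 0.0438, but their groups overlapped. This was lost without normal replicate 4, normal replicate 6, ARM replicate 4 or ARM replicate 6 (up to 0.181). Leaving out 1 library gave -0.55 (normal replicate 5) to -0.21 (normal replicate 4) for miR-126a-3p and -0.41 (normal replicate 5) to -0.20 (ARM replicate 6) for miR-126a-5p. The miR-741 and miR-743 group, singled out after its values were seen, had summed counts of 38, 9 and 35 in normal and 516, 522 and 45 in ARM.

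**Figure D1:**
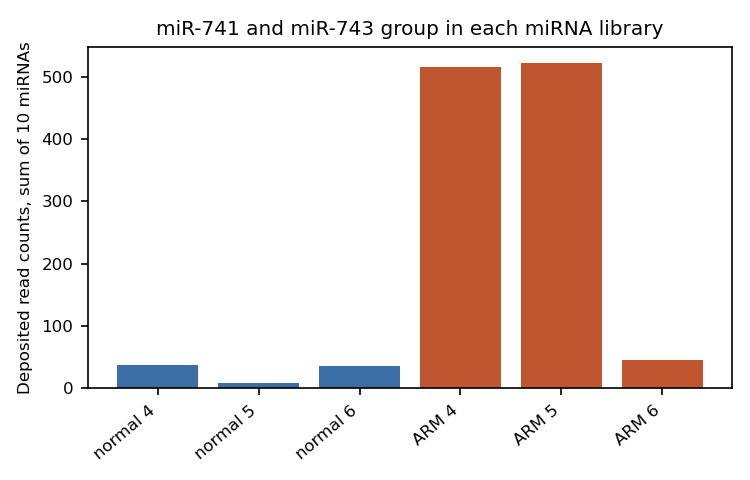
Read counts summed over the 10 miRNAs of the miR-741 and miR-743 group in each of the 6 miRNA libraries. ARM replicates 4 and 5 had 516 and 522, and the other 4 libraries 9 to 45.

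**Figure D2:**
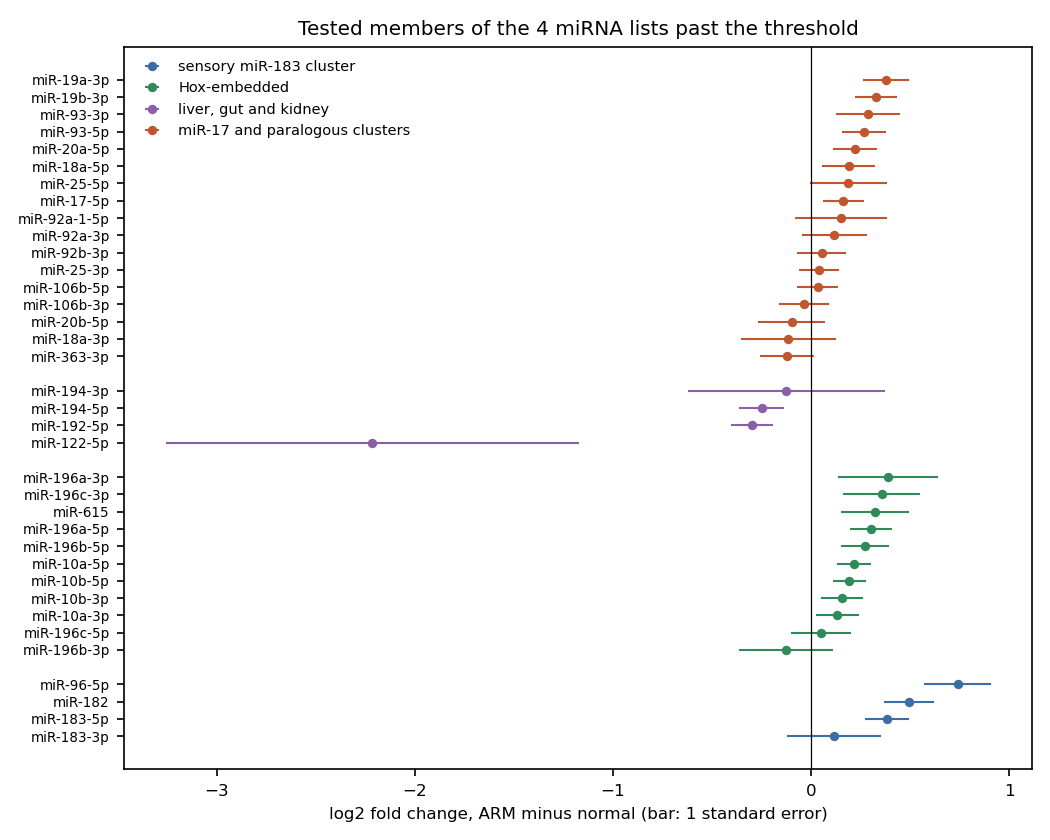
Log2 fold changes (ARM over normal) of the tested miRNAs in the 4 lists past the camera threshold, 1 point per miRNA with a bar of 1 SE. All 4 members of the miR-183 cluster lay above 0 and all 4 of the liver, gut and kidney list below 0.

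The other 12 tested miRNA lists did not pass (camera adjusted p 0.502 to 0.909), although a replicate block gave the skeletal muscle list 0.0263. Neuron-enriched miRNAs were split 7 higher and 12 lower (miR-9a-5p 0.07, miR-7a-5p -0.06), and motor neuron miRNAs 2 and 2 (miR-218a-5p -0.24, miR-17-1-3p 0.22). Oligodendrocyte lineage miRNAs were split 4 and 4 (miR-219a-2-3p 0.20, miR-138-5p 0.25), and the let-7 family 4 and 6 (let-7i-5p -0.03, let-7c-5p 0.13). The miR-125, miR-99 and miR-100 list had 7 higher and 3 lower (miR-99a-5p -0.11, miR-125b-5p -0.08). The injury list had 4 and 4 (miR-146b-5p -0.10, miR-221-3p 0.08), and the miR-34 list 1 and 4 (miR-34c-5p -0.14, miR-34a-5p -0.11). Among lists of other tissues, skeletal muscle had 2 higher and 4 lower (miR-206-3p -0.24, miR-499-5p 0.08), mesenchyme 2 and 5 (miR-143-3p -0.16, miR-199a-5p 0.16), epithelium 1 and 5 (miR-203a-3p -0.18, miR-205 0.65, or 0.045 without ARM replicate 4) and leukocytes 2 and 1 (miR-150-5p -0.27, miR-155-5p 0.12). Lists with fewer than 3 tested members were cartilage (miR-140-5p 0.09, miR-140-3p -0.24), endothelium, and pluripotency with miR-293-5p alone (-0.32). The sign turned when 1 library was left out for miR-7a-5p, let-7i-5p, miR-146b-5p, miR-221-3p, miR-34a-5p, miR-206-3p, miR-499-5p, miR-199a-5p, miR-203a-3p, miR-140-5p and, in the Dlk1-Dio3 list, miR-127-3p. The 4 erythroid miRNAs in the table had 0 counts in all 6 libraries. They were among 142 of the 753 miRNAs at 0 throughout, as were the leukocyte miRNAs miR-142-3p and miR-142-5p, so this does not show that blood RNA was absent.

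The second comparison asked which lncRNA transcripts differ between ARM and normal spinal cord. EdgeR called 16 of 13343 tested transcripts, 9 higher and 7 lower in ARM, with 798 at an unadjusted p under 0.05. Other splits of these libraries into 3 and 3 gave up to 1094 at that unadjusted p. In each of the 16, every ARM library lay on one side of every normal library. Chance gives this for 10% of unchanged transcripts, but the 16 were picked by a test on these same libraries, so it is no separate support. Among transcripts carrying the symbol of a protein-coding gene, one at Pou4f1, a sensory neuron transcription factor gene, rose from 3.17 ± 1.77 to 53.3 ± 6.78 CPM (log2 fold change 4.06, SE 0.40, edgeR adjusted p 0.0281). One at the kinesin gene Kif26b rose from 76.5 ± 5.88 to 264.5 ± 2.60 CPM (1.79, SE 0.12, edgeR adjusted p 0.0043). One at Nfe2l1, a stress-response transcription factor gene, fell from 59.9 ± 11.5 to 0.285 CPM, with 647 counts in normal and 3 in ARM (ratio 211, 95% exact binomial interval 71.9 to 1027, edgeR adjusted p 0.000527). One at Ndrg3 fell from 367 ± 50.4 to 24.5 ± 6.62 CPM (-3.91, SE 0.25, edgeR adjusted p 0.0043). These are NONRATT011163.2 (chromosome 15, 88619129 to 88620802), NONRATT009033.2 (13, 96774894 to 96776106), NONRATT005942.2 (10, 84682448 to 84688899) and NONRATT018818.2 (3, 152972161 to 153019386), in rat coordinates whose build is not given in the table.

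The other called transcripts carry AceView locus names or identifiers alone. The transcripts plochy (NONRATT018820.2, 57.9 ± 5.30 CPM in ARM) and veyshee (NONRATT016571.2, 36.8 ± 4.36 CPM in ARM) had 0 counts in all normal libraries. They were at least 207-fold and at least 132-fold higher in ARM, against a floor of 3 counts over the group. An overlapping transcript with the same locus name veyshee, NONRATT016570.2, had 49, 44 and 50 counts in normal and 58, 38 and 68 in ARM. MSTRG.5726.1 (516 ± 214 CPM in normal) and MSTRG.9548.1 (257 ± 54.3 CPM in normal) had 0 counts in all ARM libraries and were at least 1814-fold and at least 903-fold lower. The transcript chywer had 1 count in normal and 78 in ARM (ratio 79.7, 95% exact binomial interval 13.9 to 3186). Also higher were NONRATT004731.2 (6.21), cheezey (4.99), koycher (3.25) and sharza (2.76, from 38.9 ± 9.32 to 264 ± 33.6 CPM). Also lower were towaw (-4.26), LOC680656 (-3.46) and rorgar (-2.38). DESeq2 called 76 transcripts, 15 of them among the 16, and limma-voom called 16, of which 12 were shared. When 1 library was left out, 8 of the 16 were called in all 6 fits: the Kif26b, Nfe2l1 and Ndrg3 transcripts, plochy, veyshee, cheezey, towaw and MSTRG.9548.1. The transcripts chywer (edgeR adjusted p up to 0.130) and koycher (up to 0.266) were called in 0 of the 6. The Pou4f1 transcript (up to 0.112) was lost without normal replicate 1 or any of the ARM replicates, sharza (0.0529) without normal replicate 2 and MSTRG.5726.1 (0.0871) without normal replicate 1. The rorgar transcript (up to 0.138) was called only without normal replicate 3, and NONRATT004731.2 (up to 0.186) and LOC680656 (up to 0.102) only without ARM replicate 2. Without ARM replicate 1 the edgeR count was 29.

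**Figure D3:**
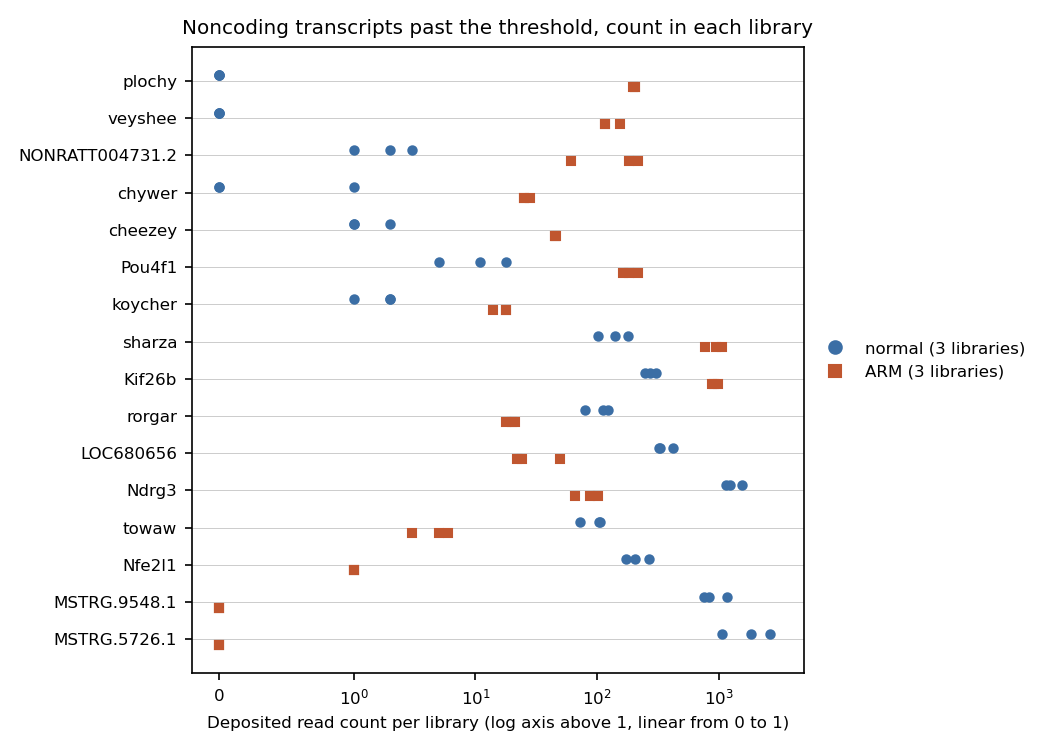
Read counts of the 16 called lncRNA transcripts, 1 point per library, on an axis that is logarithmic above 1 and linear from 0 to 1. The ARM and normal points do not overlap for any of the 16.

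Of the 16 called transcripts, 8 overlap another transcript of the table, at 7 loci. Summing the counts of all overlapping transcripts, a unit chosen after seeing the data, left 3 of the 7 loci past the edgeR threshold. The Ndrg3 and plochy transcripts overlap each other, and their summed locus was lower in ARM (-2.18, edgeR adjusted p 0.00391). The veyshee locus stayed higher (1.95, edgeR adjusted p 0.0141) and the rorgar locus lower (-2.11, edgeR adjusted p 0.0427). The Pou4f1 locus did not pass (0.18, edgeR adjusted p 0.849). Its other transcript, NONRATT011162.2, was at 461 ± 70.2 CPM in normal and 482 ± 19.5 CPM in ARM (0.06, SE 0.14). At the Nfe2l1 locus the overlapping NONRATT005943.2 and NONRATT005941.2 were at 0.0045 (SE 0.15) and 0.29 (SE 0.25). That locus did not pass (-0.77, edgeR adjusted p 0.296), nor did the loci of MSTRG.5726.1 (-0.53, edgeR adjusted p 0.791) and MSTRG.9548.1 (-0.59, edgeR adjusted p 0.794), where the overlapping MSTRG.5726.2 and MSTRG.9548.2 were at 2.14 (SE 0.49) and 1.82 (SE 1.31). The counts of MSTRG.9548.2 in the normal libraries were 376, 265 and 0.

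**Figure D4:**
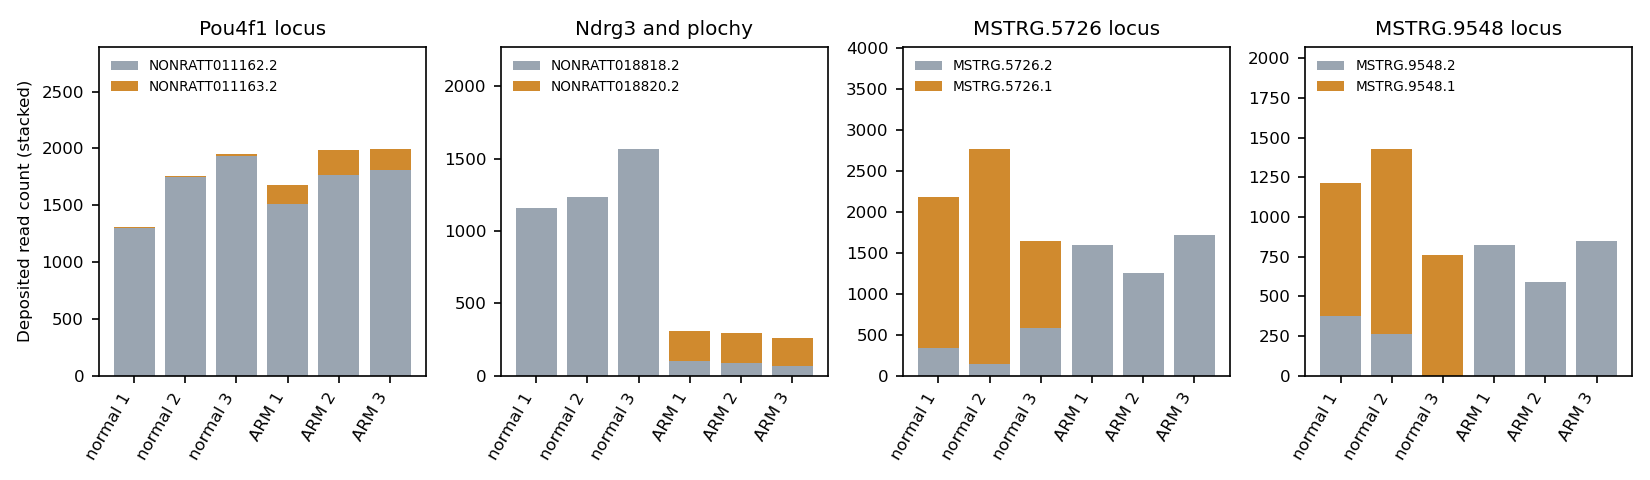
Stacked read counts of overlapping transcripts at 4 loci with called transcripts in each of the 6 lncRNA libraries. The Pou4f1 transcript that rose is a small part of the summed counts of its locus.

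Of the lncRNA lists, 4 of 14 were called by camera, all higher in ARM, and these calls rest on the Meg3 and Pou4f1 loci. Of the members, only the Pou4f1 transcript passed over all transcripts. The imprinted list and the microRNA-host list rest on the same 9 transcripts of Meg3, a maternally expressed lncRNA, of which 8 had higher estimates (range -0.51 to 1.18, median 0.33). The most abundant Meg3 transcript was at 13188 CPM in normal and 15244 CPM in ARM (0.21, SE 0.11). Camera gave each list an adjusted p of 0.00187 (adjusted p = 0.130 with an estimated correlation), and 2 members passed adjusted over the list alone. Of these, NONRATT024620.2 passed in 2 of the 6 fits that left out 1 library (without normal replicate 3 or ARM replicate 1) and NONRATT024623.2 in 1 (without normal replicate 3), with edgeR adjusted p up to 0.0945. Nuclear and abundant lncRNAs, which include the same 9 Meg3 transcripts beside Miat, Gas5 and a transcript with the locus name Rmrp, had 15 higher and 3 lower of 18, with a camera adjusted p of 0.00835 (adjusted p = 0.130 with an estimated correlation) and 3 members past the threshold adjusted over the list alone, which each passed in 1 of the 6 fits that left out 1 library, that without normal replicate 3 (edgeR adjusted p up to 0.151). In a check chosen after seeing the data, removing the Meg3 transcripts left a camera adjusted p of 0.532. Transcripts at spinal patterning genes had 6 higher and 3 lower of 9, with a camera adjusted p of 0.0344 (adjusted p = 0.193 with an estimated correlation). Without the called Pou4f1 transcript, a check also chosen after seeing the data, it was 0.673, with 5 of 8 higher. The estimated correlations were -0.122 for the imprinted and microRNA-host lists, -0.0390 for the nuclear list and -0.0285 for the patterning list. All were below the preset 0.01, so a higher correlation does not explain why these calls were lost with the estimates. Without normal replicate 3 or ARM replicate 3, 2 lists were called: the nuclear list had camera adjusted p of 0.0714 and 0.0682, and the patterning list the same values. The patterning list was also lost without normal replicate 1 (0.206), normal replicate 2 (0.0671) or ARM replicate 1 (0.133).

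The remaining 10 tested lncRNA lists did not pass (camera adjusted p 0.0643 to 0.807). All 4 tested transcripts at Hox genes had higher estimates (Hoxb8 0.27, Hoxd9 0.32), as did all 3 at thyroid hormone responsive genes (Thra 0.33, Reln 0.13; fry adjusted p 0.0222), and 9 of 11 at neuron genes (Rbfox3 0.05, Elavl3 0.32). At apoptosis genes 2 of 3 were higher (camera adjusted p 0.0933, or 0.0418 without normal replicate 2). At cell cycle genes all 3 had lower estimates (Mki67 -0.45, Top2a -0.09), but Mki67 was at 0.58 without normal replicate 1 and 0.13 without ARM replicate 2, and Top2a at 0.23 without normal replicate 2, 0.0023 with limma-voom and 0.21 in the locus sum. Transcripts at astrocyte and progenitor genes had 2 higher and 5 lower (Nfib 0.30, Slc1a2 -0.08), those at motor neuron genes 1 and 2 (Foxp1 0.01, Lhx3 -0.39), and endothelium and meninges 2 and 2 (Pecam1 -0.08, Col3a1 0.18). Transcripts at retinoic acid and Wnt genes had 3 and 2 (Ctnnb1 0.08, Axin2 0.29), and small nucleolar RNA hosts 7 and 4 (Snhg11 -0.03, Gas5 0.13). Lists with fewer than 3 tested transcripts were cartilage and bone (Col2a1 1.64, from 0.41 without ARM replicate 1 to 2.88 without normal replicate 3, and Col1a1 -0.17), oligodendrocytes (1 tested transcript), ganglion and Schwann cells (Ntrk2 0.18) and neural lncRNAs, where Miat, at 4430 ± 129 CPM in normal and 5559 ± 103 CPM in ARM (0.33, SE 0.08), passed adjusted over the list alone, of which it was the 1 tested member. The sign also turned for Col1a1, Pecam1, Col3a1, Foxp1, Ctnnb1, Rbfox3, Ntrk2 and Snhg11 when 1 library was left out. Erythroid, microglia and skeletal muscle lists had 0 tested transcripts. The X inactivation and Hox cluster lncRNA lists matched none by name, which does not show that such transcripts were absent. The 5 most abundant transcripts were MSTRG.113.4 (0.02), stawflu (0.22), gokla (0.31), byvu (0.18) and the Meg3 transcript.

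The Meg3 locus hosts the Dlk1-Dio3 miRNA cluster, so host and miRNAs were set side by side from the separate libraries, whose samples carry the same label codes. Of the 78 tested Dlk1-Dio3 miRNAs, 39 had higher and 39 lower estimates (median 0.00, range -0.60 to 0.66), with miR-127-3p at 0.05 and miR-379-5p at -0.19. Camera gave this list an adjusted p of 0.746. The difference between the Meg3 transcripts and these miRNAs was not tested.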

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

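The tests on counts summed over overlapping transcripts and on 2 shortened lncRNA lists were chosen only after the result was seen, and the other alternatives before. For single miRNAs, where edgeR called 0 with 29 at an unadjusted p under 0.05, DESeq2 called 6 and leaving out 1 library gave 0 to 9, the 9 without ARM replicate 6 and all from the miR-741 and miR-743 group. The replicate numbers showed no pairing of the miRNA samples: same-number correlations were -0.10, -0.15 and 0.03 against -0.23 to 0.28 for other pairs. With 3 same-number pairs this cannot exclude a pairing. A replicate block called 5 miRNAs and 5 miRNA lists, the 4 and skeletal muscle (camera adjusted p 0.0263). No paired analysis was possible for lncRNA, where the normal columns were matched to the group alone. Of miRNA lists, an estimated correlation and fry each called 0, and leaving out 1 library gave 0 to 7 (2 without normal replicate 4, 7 without ARM replicate 4, 0 without ARM replicate 6). For lncRNA transcripts, DESeq2 called 76, no filter 9, the stricter filter 8, and leaving out 1 library 19 to 29 (29 without ARM replicate 1). Of lncRNA lists, an estimated correlation called 0, fry 5 (the same 4 and the thyroid hormone responsive genes, adjusted p 0.0222) and leaving out 1 library 2 to 4 (2 without normal replicate 3 and without ARM replicate 3). The nuclear list had a camera adjusted p of 0.532 without Meg3 and the patterning list 0.673 without its called transcript. RLE and total-count scaling kept all 16 transcript calls. The stricter filter tested fewer transcripts; the cause of the other changes was not tested. Pseudocount alternatives do not apply to counts.

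The 16 called transcripts had 197 values under alternatives: 142 kept direction and call, 54 kept direction only, and 1 reversed. That was plochy, at -2.18 because the sum includes Ndrg3. The 72 other features followed had 956 values, of which 8 passed the threshold and 40, in 24 features, changed sign. Leaving out 1 library gave ranges of -2.74 to 0.58 for Mki67, -0.49 to 0.26 for Col1a1, -0.41 to 0.23 for Top2a, -0.16 to 0.056 for Pecam1, -0.045 to 0.16 for Rbfox3, -0.20 to 0.58 for Ntrk2, -0.11 to 0.025 for Snhg11, -0.57 to 0.65 for Foxp1, -0.033 to 0.20 for Ctnnb1 and -0.14 to 0.36 for Col3a1. For miRNAs they were -0.086 to 0.014 for let-7i-5p, -1.38 to 0.14 for miR-1-3p, -2.84 to 0.64 for miR-122-5p, -0.010 to 0.10 for miR-127-3p, -0.013 to 0.16 for miR-140-5p, -0.20 to 0.054 for miR-146b-5p, -0.042 to 0.32 for miR-199a-5p, -0.37 to 0.10 for miR-203a-3p, -1.05 to 0.23 for miR-206-3p, -0.022 to 0.17 for miR-221-3p, -0.0020 to 0.088 for miR-25-3p, -0.17 to 0.0092 for miR-34a-5p, -0.093 to 0.22 for miR-499-5p and -0.14 to 0.069 for miR-7a-5p. Top2a was at 0.0023 with limma-voom and 0.21 when summed. Foxp1 was at -0.015 with DESeq2, -0.0025 with RLE, -0.0036 with no filter and -0.056 when summed, and Snhg11 at 0.015 with total-count scaling. The cause was not tested.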

Other observations

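The tests of what overlapping partners took up and the comparison of overlap among all-or-none transcripts were chosen only after the result was seen. The 10 miRNAs of the miR-741 and miR-743 group, picked because alternatives called them, had summed counts of 516 and 522 in ARM replicates 4 and 5, 45 in ARM replicate 6, and 9 to 38 in the normal libraries.

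Each count of calls was compared with those of the 10 splits of its 6 libraries into 3 and 3, which are too few for a share under 0.05. For single miRNAs 10 of the 10 splits gave a count as large (real 0, highest other 0). For miRNA lists 1 did (real 4, highest other 3), for lncRNA transcripts 1 (real 16, highest other 9), for lncRNA lists 1 (real 4, highest other 0), and for transcripts at most 1 count in one phenotype and at least 10 in the other 1 (real 11, highest other 8). The 4 lncRNA lists rest on the Meg3 and Pou4f1 loci and are not 4 separate results. In the number at an unadjusted edgeR p under 0.05 the real split was not the highest. It gave 29 miRNAs against up to 47 in another split, and 798 transcripts against up to 1094.

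The first pattern is the all-or-none transcripts, 413 with at most 1 count in some libraries and at least 10 in all others, whatever the phenotype: of the 248 that passed the filter and were tested, 177 (71.4%) overlap another transcript, against 4275 of the 13095 other tested transcripts (32.6%; two-sided Fisher's exact p = 9.55e-35, transcripts not being independent). Reads assigned to another overlapping transcript of the same locus may account for part of the calls: the median absolute log2 fold change of the 7 summed loci was 0.770 (bootstrap bounds 0.527 to 2.11), between the limits set for and against. Partners in the table took up 3.85% of the Nfe2l1 transcript's change in CPM the other way (upper bound of 2 SE 38.1%), 1.72% for rorgar (37.4%), -6.06% for veyshee (19.4%) and 16.9% for Ndrg3 (34.6%), which argues against reassignment among them as the whole cause there. The values were 65.2% (27.7% to 103%) for MSTRG.5726.1, 60.1% (12.4% to 108%) for MSTRG.9548.1 and -42.4% (-216% to 131%) for Pou4f1, so reassignment may hold at the MSTRG loci and stays open at Pou4f1. Reads assigned to transcripts outside the table, such as messenger RNAs, and the 8 calls with no partner were not tested, and phenotype remains among the open explanations. The plochy transcript was not tested on its own either. Its change was 57.1 CPM against -337 CPM for the overlapping Ndrg3 transcript, so reassignment stays open for it.

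The second pattern is the miR-183 cluster and the Hox-embedded miRNAs, called as lists and not with an estimated correlation (adjusted p = 0.202 for each), and the called Pou4f1 transcript. Of the Hox-embedded miRNAs 10 of 11 had higher estimates. A larger share of sensory ganglion tissue in the ARM samples could raise the cluster. At the Pou4f1 locus the called transcript rose by 49.5 CPM and the overlapping one by 21.0 CPM. Their sum rose by 70.5 CPM (SE 43.0). The overlapping transcript had 1301 to 1935 counts in the normal libraries, against 5 to 18 for the called one. The log2 fold changes of the summed locus (0.18) and of the called transcript (4.06) start from unlike levels, so they do not decide this. The ganglion and Schwann list had 1 tested transcript, Ntrk2 at 0.176, and 0 transcripts of Hox10 to Hox13 loci were tested for a more caudal level of dissection in the ARM samples, too few to decide either. These explanations and an effect of the malformation or of ethylenethiourea cannot be told apart here.

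The third pattern is the miR-741 and miR-743 group in 2 of the 3 ARM libraries. Gonadal tissue or RNA in those libraries is a candidate explanation. The gonadal miRNA miR-202 had 0 counts in ARM replicates 4 and 5, 1 count in normal replicate 6 and 0 in the other libraries. That excludes nothing, since miR-202 was at or near 0 in every library, which is too low to compare them. The blood-cell miRNAs miR-451 and miR-142 had 0 counts in all 6 libraries, so 0 counts here need not mean an absent tissue. No biological explanation was tested, since the design names none that divides the ARM libraries.

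There were 19 lncRNA transcripts at least 100-fold apart between 1 library and all 5 others. Among them, 2 neighbours on chromosome X set normal replicate 1 apart: parbee (74324613 to 74331978) had 50 counts there and 14386 to 56874 in the other 5 libraries, and NONRATT031073.2 (74332849 to 74341256) had 18 there and 6396 to 22326 in the others. The X inactivation list was matched by name and matched no transcript, so whether these 2 belong to it is not known. The labels do not give fetal sex, and 0 transcripts lie on chromosome Y. Whether sex differed between the libraries or groups was therefore not tested, and no fit accounts for it.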
